A study of Homo sapiens with 9 samples.

How the data were processed

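RNA of THP-1 cells, a human monocytic leukaemia line, was profiled in 9 libraries that the labels put into 3 groups of 3. These were cells without ectosomes (control), cells given ectosomes of Huh7 hepatoma cells carrying a scramble shRNA, and cells given PKM2-knockdown ectosomes. The knockdown was read here as one in the donor Huh7 cells, which the labels do not spell out. Ectosomes are vesicles that bud from the plasma membrane. Per the labels' protocols, RNA was extracted with Trizol, 3 µg per sample went into libraries made with the NEBNext Ultra RNA kit, and these were sequenced on an Illumina HiSeq instrument. The dose and preparation of the ectosomes and the time of incubation are not given in the sources used here. The labels number the replicates and do not say whether they came from separate cultures.

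The authors deposited 1 table of raw read counts per gene symbol for all 9 libraries, with no normalization. HISAT2 2.0.5, featureCounts 1.5.0-p3 and the GRCh38/hg38 genome are named in the submitters' processing notes. The annotation release, the strand setting and any filter are not given in the sources used here, so reads of overlapping genes and of genes on opposite strands cannot be told apart, and genes with near-identical copies may have exchanged reads. The table holds 30000 rows, the lowest row total over the 9 libraries being 4 counts, so rows below that total are not analysed here. Of the rows, 355 repeat the name of an earlier row, over 60 symbols, and were kept as separate rows. Names of 24 rows had been turned into dates and were kept without a gene name. Of the row names, 99.9% were found in GENCODE release 29, which was used for gene types, coordinates, length and GC content.

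Totals ran from 17744587 to 23864381 counts per library. Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Rows with too few counts were removed with filterByExpr by group, which left 18437 rows holding at least 99.8% of the counts of every library. Libraries were scaled by TMM, and all 9 libraries were fitted in 1 quasi-likelihood model with group as the only term, which left 6 residual degrees of freedom. The common biological coefficient of variation was 13.3%. The 3 comparisons were scramble ectosomes against control, PKM2-knockdown against scramble ectosomes, and PKM2-knockdown ectosomes against control. As both kinds of ectosomes were set against the same control, the middle comparison is also the test of the difference between their effects. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all rows tested was the threshold. Every adjusted p of a gene is from this edgeR quasi-likelihood test unless another tool is named. Levels are TMM-scaled CPM, computed here from the deposited counts. Fold changes are model estimates with a small prior count. Each SE is the absolute log2 fold change divided by the square root of the F statistic of its quasi-likelihood test. It is an approximation and may be too small where a group had few reads. Where all libraries of a group had 0 reads, the fold is given as a lower bound against 3 counts over the group, and where a group had 1 to 3 reads, as the ratio of CPM with an exact 95% interval. Such bounds and intervals cover counting error only, as reads without molecular identifiers are not independent molecules.

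The genes named in the text follow a rule written before the data were examined. It takes PKM, STAT3, CCL1 and CCR8 whatever their result. It takes the 10 largest rises and the 10 largest falls in each of the comparisons of scramble ectosomes with control and of the 2 kinds of ectosomes, and 5 and 5 for PKM2-knockdown ectosomes against control. These had to pass the threshold, have a mean of at least 5 CPM, have every library of 1 group above every library of the other, and bear a symbol that is not clone-based. It also takes up to 4 members with the smallest p of each of 23 gene lists, of which the text names some as examples, chosen after their values were seen. The lists, also fixed before the data were examined, cover macrophage differentiation markers, myeloid differentiation transcription factors, progenitor and granule genes, cytokines and chemokines, classically and alternatively activated macrophage markers, NF-kB targets, STAT3 targets, type I interferon response, glycolysis, hypoxia response, cholesterol synthesis, LXR target and lipid handling genes, amino acid and ER stress genes, MAPK immediate-early and feedback genes, cell cycle, MHC class II, lysosome and phagocytosis, matrix, protease and coagulation genes, hepatocyte transcripts, mitochondrially encoded genes, histone genes and cytosolic ribosomal proteins. For each list, members past the threshold were counted with p adjusted over all rows and over the list alone. Each list was compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and, beside it, an estimated one. Benjamini-Hochberg adjustment was over the 23 lists of a comparison. The correlation was estimated from all 9 libraries in every comparison, and not without control replicate 3. Some genes are on several lists. CCR8 is not analysed here.

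Comparisons that share libraries share their chance values. References were therefore computed for genes moved by scramble ectosomes and the other way by the knockdown, and for genes moved the same way by both kinds. These overlaps are given beside the overlap of independent lists and beside 20 simulations in which no group differed. The correlation and covariance of the log2 fold changes are given beside these simulations too. Other overlaps between comparisons have no such reference. Replicates were compared by a chi-square test of their counts and by Pearson correlation across genes of log2 CPM. Principal components were computed on log2(CPM + 1).

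The procedure was tested on simulated counts drawn from the real means and library sizes, with genes changed by known folds among the 18437 rows. For scramble ectosomes against control, 14.9% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 77.3% of those changed 4-fold were recovered, and 9 of 108 calls (8.33%) were false. Of the 4-fold genes, 97.4% were recovered at a mean of at least 5 CPM and 48.1% under 5 CPM. For PKM2-knockdown against scramble ectosomes the recovered shares were 25.4%, 61.2% and 92.4%, with 7 of 126 calls (5.56%) false, and the 4-fold shares at and under that level were 97.7% and 82.6%. For PKM2-knockdown ectosomes against control they were 28.4%, 62.7% and 88.6%, with 9 of 248 calls (3.63%) false, and 98.8% and 72.0% by level. A minimum share of 4-fold genes recovered had been set for this check, and scramble ectosomes against control missed it. After that result was seen, the minimum was first lowered and then dropped, and replaced by requirements on the estimated folds, the false share and the set test. The simulation itself was not changed. Absence of a call for a gene of low count is therefore weak evidence.

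Alternatives chosen before the data were examined were DESeq2-type size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, the estimated correlation of the set test, and leaving out each replicate in turn. Chosen after seeing the data were scaling by library totals alone and, for list counts and for genes beyond both other groups, leaving out control replicate 3.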

Results

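THP-1 cells were profiled by RNA-seq after incubation with ectosomes, vesicles that bud from the plasma membrane, of the hepatoma line Huh7. The 9 libraries fell into 3 groups of 3: control cells, cells given ectosomes of scramble-shRNA Huh7 cells, and cells given PKM2-knockdown ectosomes. These last were read here as ectosomes of Huh7 cells with PKM2 knocked down. PKM2 is an isoform of pyruvate kinase, encoded by PKM. The control libraries held 17916081, 21184775 and 17744587 counts, the scramble-ectosome libraries 23864381, 20948331 and 22921616, and the PKM2-knockdown-ectosome libraries 19514119, 20777931 and 18593808. Mitochondrially encoded genes took 4.27% to 4.90% of the counts of a library. Values with ± are means and SDs over n = 3 libraries. As nothing says that the replicates came from separate cultures, the p-values measure only the spread between these libraries, which may be technical.

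The libraries separated by group. The main axis of a principal component analysis carried 63.0% of the variance and set control cells at the opposite end from cells given scramble ectosomes, with the PKM2-knockdown group between them. The next axis carried 29.1% and set the PKM2-knockdown group apart from both others. Control replicate 3 stood apart from the other controls. The chi-square of its counts per degree of freedom was 49.6 against control replicate 1 and 46.0 against control replicate 2, while these differed from each other by 5.18. Against the mean of control replicates 1 and 2 it had 234 genes at least 2-fold higher and 995 at least 2-fold lower, where control replicate 2 against 1 had 36 and 33 (pseudocount 0.5 CPM).

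**Figure D1:**
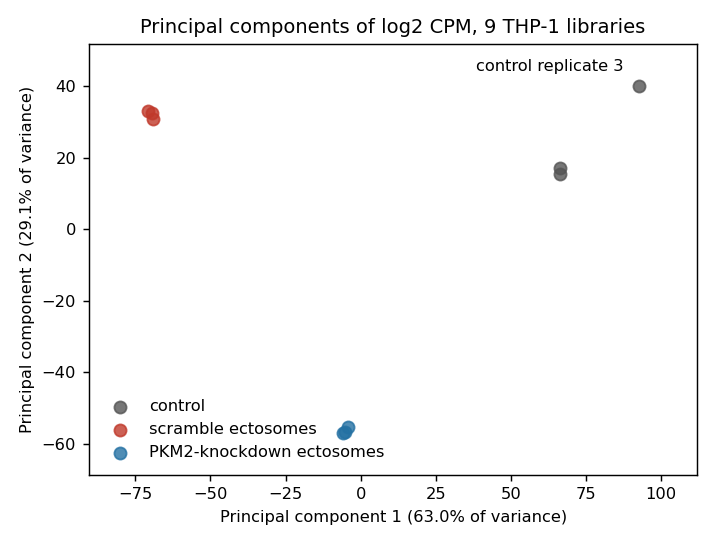
Principal components 1 (x axis, 63.0% of the variance) and 2 (y axis, 29.1%) of log2(CPM + 1) for the 9 libraries, 1 point per library, coloured by group. The libraries of each ectosome group lie close together, and control replicate 3 lies away from control replicates 1 and 2.

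PKM transcript, counted in the THP-1 libraries without separating its isoforms, was higher with both kinds of ectosomes. PKM (chromosome 15, 72199029 to 72231822, minus strand, GRCh38) stood at 650 ± 195 CPM in control cells, 3500 ± 108 CPM with scramble ectosomes and 2313 ± 137 CPM with PKM2-knockdown ectosomes. It rose 5.38-fold with scramble ectosomes (log2 fold change 2.43, SE 0.19, adjusted p = 1.03e-06) and 3.56-fold with PKM2-knockdown ectosomes (log2 fold change 1.83, SE 0.19, adjusted p = 1.70e-05). The control libraries held 789, 734 and 428 CPM, the lowest in control replicate 3. Between the 2 kinds of ectosomes PKM was 1.51-fold lower with the knockdown (log2 fold change -0.60, SE 0.18, adjusted p = 0.0145), a call that ended without PKM2-knockdown replicate 1 (adjusted p = 0.0544) and with scaling by library totals alone (adjusted p = 0.0752), the adjusted p ranging from 1.54e-08 to 0.0752 over its alternatives. As the knockdown was read here as one in the donor Huh7 cells, these counts check nothing about it.

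STAT3, a transcription factor downstream of cytokine receptors (chromosome 17, 42313324 to 42388568, minus strand), rose from 120 ± 23.2 CPM in control cells to 323 ± 3.35 CPM with scramble ectosomes, 2.69-fold (log2 fold change 1.43, SE 0.12, adjusted p = 2.18e-06). With PKM2-knockdown ectosomes it stood at 175 ± 5.78 CPM, 1.84-fold below scramble ectosomes (adjusted p = 0.000106) and 1.46-fold above control (adjusted p = 0.00327). The chemokine gene CCL1 (chromosome 17, 34360328 to 34363231, minus strand) had 0 reads in the controls, 7 over the scramble-ectosome libraries and 100 over the PKM2-knockdown-ectosome libraries. Its level with PKM2-knockdown ectosomes was at least 33.0-fold above control (adjusted p = 0.000528) and 14.1-fold above scramble ectosomes (adjusted p = 0.00150), or 29.6-fold without scramble replicate 1. The difference between scramble ectosomes and control did not pass the threshold for CCL1 (adjusted p = 0.0899), but did without scramble replicate 3 (adjusted p = 0.0432) and with the DESeq2 Wald test (adjusted p = 0.0200), in a range of 0.0200 to 0.255. The receptor gene CCR8 is not analysed here.

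**Figure D2:**
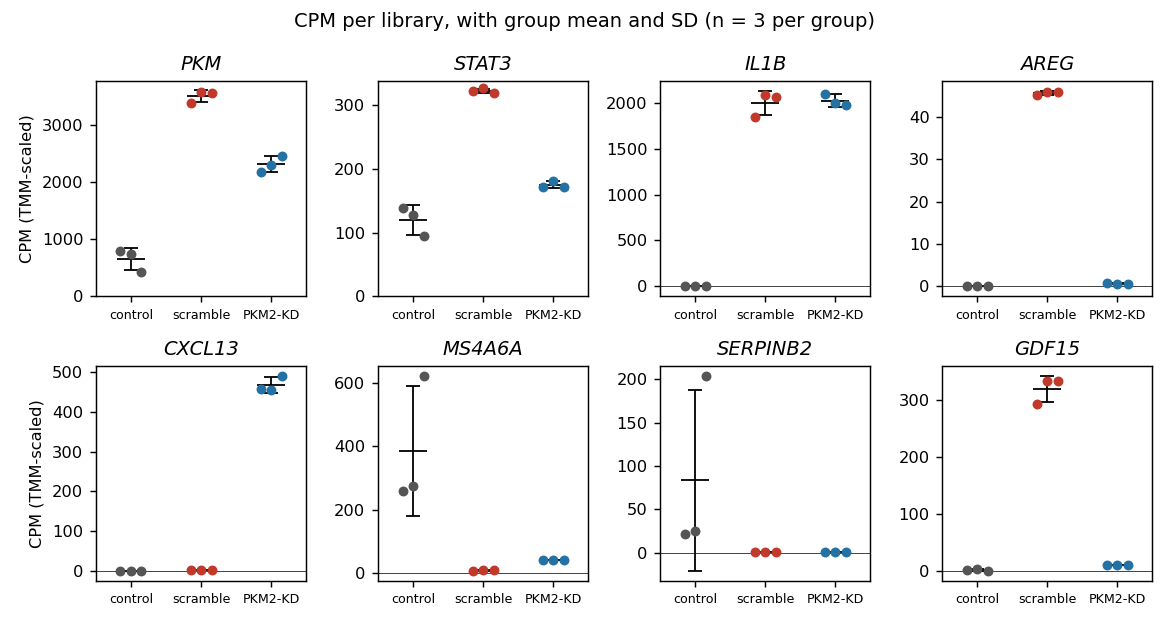
Level in CPM (y axis, linear scale) of PKM, STAT3, IL1B, AREG, CXCL13, MS4A6A, SERPINB2 and GDF15 in each library, 1 point per library by group (x axis), with mean and SD bars over n = 3. PKM and STAT3 are highest with scramble ectosomes, at 3500 and 323 CPM, IL1B is at 1997 and 2024 CPM with the 2 kinds, and CXCL13 reaches 468 CPM with PKM2-knockdown ectosomes.

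The comparison of scramble ectosomes with control asks what ectosomes of hepatoma cells carrying a scramble shRNA change in monocytic cells. Cells given scramble ectosomes expressed cytokines, NF-kB targets and ER stress genes at higher levels than control cells, and progenitor, granule and cell cycle genes at lower levels. Each of these set calls was lost with an estimated correlation (adjusted p from 0.222 to 0.484). IL1B, the gene of interleukin-1 beta, rose from 4.99 ± 4.13 to 1997 ± 134 CPM, 394-fold (log2 fold change 8.62, SE 0.66, adjusted p = 8.30e-07). The EGF receptor ligand AREG rose from 0.0820 ± 0.0800 to 45.7 ± 0.483 CPM, 512-fold, or 841-fold without control replicate 1. MYB, a transcription factor of immature blood cells, fell from 541 to 31.3 CPM, 17.3-fold (adjusted p = 1.39e-08). Of 18437 genes tested, 6377 were higher and 6115 lower, 12492 in all, and 3335 and 3413 of these differed at least 2-fold.

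Among the 10 largest rises were 2 genes with 0 control reads: NRG1, the gene of the ligand neuregulin 1, at 60.4 ± 1.94 CPM (at least 1208-fold), and the mucin gene MUC5AC at 14.7 ± 2.36 CPM (at least 292-fold). IGFBP5, which encodes a binding protein of insulin-like growth factors, had 2 control reads and rose to 21.1 ± 2.37 CPM, a ratio of 630 (95% interval 174 to 5209), with a fitted fold of 534 or, without control replicate 2, 348. The chemokine gene CXCL3 rose from 0.449 to 240 CPM (511-fold), THBS1, encoding the matrix protein thrombospondin 1, from 0.987 to 356 CPM (346-fold), and INHBA, encoding a subunit of activin A, from 0.209 to 83.7 CPM (352-fold, or 1383-fold without control replicate 2). INHBA overlaps INHBA-AS1 on the other strand. The pseudogenes HSD3BP5, at 35.04 CPM against 2 control reads (ratio 1055, 95% interval 292 to 8719), and HMGN2P46, at 35.5 against 0.0792 CPM, complete the 10, both uncertain because they resemble or overlap other genes. Adjusted p of the 10 ran up to 8.30e-07.

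Among the 10 largest falls, TERT, encoding the catalytic subunit of telomerase, stood at 34.2 ± 26.6 CPM in control cells and had 2 reads over the scramble-ectosome libraries, a ratio of 1011 (95% interval 280 to 8358), with a fitted fold of 889 or, without control replicate 3, 492. CCR2, the receptor of the monocyte chemokine CCL2, fell from 77.7 ± 45.6 to 1.23 ± 0.150 CPM (62.3-fold, or 41.2-fold without control replicate 3). MS4A6A fell from 385 ± 206 to 7.84 ± 1.32 CPM (49.1-fold), MS4A4E 53.1-fold, the coagulation factor gene F13A1 158-fold, VAT1L 152-fold, RGMA 50.5-fold and ANXA8 48.8-fold. Counts of MS4A4E and MS4A4A, which overlap on opposite strands, and of ANXA8, which has near-identical copies, are uncertain. SERPINB2 and SERPINB10, protease inhibitor genes that overlap on the same strand, fell 146-fold and 107-fold, or 40.6-fold and 37.5-fold without control replicate 3. SERPINB2 varied widely between the controls (83.5 ± 105 CPM), and the DESeq2 Wald test gave it no adjusted p. Adjusted p of the 10 ran up to 0.000124.

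Inflammatory lists rose with scramble ectosomes. Of 29 cytokines and chemokines, 23 rose and 0 fell, with a median log2 fold change of 3.58 (3.53 with CCL1 at its bound; camera adjusted p = 3.05e-18, and adjusted p = 0.222 with an estimated correlation). CCL22 rose 19.0-fold, OSM 18.9-fold and LIF 207-fold. All 20 NF-kB targets rose (median log2 2.45; adjusted p = 2.73e-10, and adjusted p = 0.397 with an estimated correlation), among them BCL2A1 51.0-fold, TRAF1 49.3-fold and NFKB1 7.43-fold. Of 13 classically activated macrophage markers, 11 rose and 2 fell (median log2 3.84, or 3.18 with 1 member at its bound; adjusted p = 3.39e-07, and adjusted p = 0.20 with an estimated correlation), such as CCR7, from 0.372 to 44.5 CPM. Of 28 type I interferon response genes, 26 rose and 1 fell (median log2 2.36; adjusted p = 0.000822, and adjusted p = 0.751 with an estimated correlation), with ISG15 at 24.6 and 236 CPM. In control replicate 3 these lists already stood below control replicates 1 and 2, with median log2 differences of -1.23 for cytokines, -1.48 for NF-kB targets, -1.11 for classically activated markers and -2.07 for interferon genes. Without that library 24 cytokines rose and 1 fell, 11 classically activated markers rose and 1 fell, and the other counts were the same.

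Signalling and stress genes rose as well. The MAPK, STAT3 target and transcription factor lists share members, so their results are not separate evidence. Of 20 STAT3 targets, 15 rose and 4 fell (median log2 1.90; adjusted p = 6.35e-05, and adjusted p = 0.403 with an estimated correlation), with PIM2 5.56-fold and TIMP1 9.19-fold higher. Of 24 MAPK immediate-early and feedback genes, 19 rose and 1 fell (median log2 2.55; adjusted p = 3.51e-10, and adjusted p = 0.25 with an estimated correlation), including the phosphatase genes DUSP5 (44.96-fold) and DUSP6 (14.2-fold). Of 21 amino acid and ER stress genes, 18 rose and 0 fell (median log2 1.94; adjusted p = 4.49e-07, and adjusted p = 0.484 with an estimated correlation). The ER chaperone gene HSPA5 went from 342 to 4552 CPM (13.3-fold) and the stress-induced factor gene ATF3 from 3.03 to 130 CPM (42.0-fold). Of 20 matrix, protease and coagulation genes, 17 rose and 3 fell (median log2 2.19; adjusted p = 2.45e-05, and adjusted p = 0.25 with an estimated correlation), TIMP2 being 3.90-fold lower. Of 24 myeloid differentiation transcription factors, 18 rose and 3 fell (median log2 1.36; adjusted p = 0.000916, and adjusted p = 0.560 with an estimated correlation), RUNX3 rising 8.43-fold and IRF8 falling 10.7-fold. In control replicate 3 the median log2 difference from the other controls was -0.41 for STAT3 targets, -0.81 for MAPK genes, -0.91 for ER stress genes, -0.82 for matrix genes and -0.76 for the transcription factors. Without it 15 and 4, 20 and 2, 18 and 1, 17 and 3, and 19 and 4 members rose and fell.

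Most progenitor, granule and cell cycle genes were lower with scramble ectosomes. Of 16 progenitor and granule genes, 0 rose and 15 fell (median log2 -3.30; adjusted p = 3.57e-10, and adjusted p = 0.25 with an estimated correlation). The granule genes AZU1 and ELANE fell 12.8-fold and 9.84-fold. In control replicate 3 this list lay above the other controls by a median log2 difference of 0.82, and without it the count was the same. Of 32 cell cycle genes, 7 rose and 19 fell (median log2 -1.68; adjusted p = 1.94e-08, and adjusted p = 0.25 with an estimated correlation), with the replication factor genes MCM2 and MCM4 lower by 7.59-fold and 5.13-fold and E2F1 by 5.33-fold. Without control replicate 3 the cell cycle count was 11 and 19.

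The remaining lists did not pass the set test against control. Of 19 macrophage differentiation markers 8 rose and 5 fell, with LGALS3 6.04-fold higher and TREM2 8.20-fold lower (adjusted p = 0.579). Of 19 hypoxia response genes 11 rose and 1 fell (adjusted p = 0.0772, but 0.0422 without control replicate 2, 0.0152 without scramble replicate 1 and 0.0155 with no filter on low counts, in a range of 0.0152 to 0.751). Of 22 glycolysis genes 9 rose and 5 fell (adjusted p = 0.196), PFKFB3 and the glucose transporter gene SLC2A3 rising 8.25-fold and 21.1-fold. Of 24 lysosome and phagocytosis genes 14 rose and 4 fell (adjusted p = 0.0850, but 0.0279 with no filter on low counts, in a range of 0.0279 to 0.558). Of 33 ribosomal protein genes 1 rose and 21 fell (adjusted p = 0.0586, but 0.0184 without control replicate 2, 0.0387 without scramble replicate 3 and 0.00820 with no filter, in a range of 0.00820 to 0.863). Of 23 cholesterol synthesis genes 8 rose and 6 fell (adjusted p = 0.786), of 18 LXR target and lipid handling genes 8 rose and 8 fell (adjusted p = 0.839), and of 11 MHC class II genes 2 rose and 4 fell (adjusted p = 0.889). Of 11 alternatively activated macrophage markers 3 rose and 4 fell (adjusted p = 0.260, but 0.0466, lower as a set, without control replicate 3, in a range of 0.0466 to 0.484). Of 9 histone genes 6 rose and 0 fell (adjusted p = 0.332) and of 13 mitochondrially encoded genes 3 rose and 0 fell (adjusted p = 0.786). Of 28 hepatocyte transcripts 7 had enough counts to be tested, 2 of which rose and 2 fell (adjusted p = 0.786). Leaving out control replicate 3 gave counts of 11 and 3 for hypoxia, 9 and 7 for glycolysis, 14 and 6 for lysosome, 1 and 23 for ribosomal protein, 9 and 11 for cholesterol synthesis, 8 and 9 for LXR target, 2 and 5 for alternatively activated, 6 and 1 for histone, 7 and 0 for mitochondrially encoded and 2 and 1 for hepatocyte genes, and the same for the other lists of this paragraph. Median, mean and set test differed in sign for the LXR, MHC class II and hepatocyte lists.

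Adjusted over the list alone, the counts higher and lower with scramble ectosomes changed for MHC class II (2 and 3), lysosome (14 and 5), hepatocyte (2 and 3) and mitochondrially encoded genes (1 and 0) only. Of the genes tested, 71.3% had every library of 1 group above every library of the other, where chance gives 10%. TMM set the median log2 fold change of all genes near 0, and library totals alone moved it by -0.21, with the share of calls that were rises moving from 51.0% to 40.2%. Under that scaling the list medians changed sign for glycolysis (0.19 to -0.02), cholesterol synthesis (0.04 to -0.16) and mitochondrially encoded genes (0.13 to -0.08), and the counts became 7 and 8, 7 and 10, and 1 and 3. Many other counts changed as well, some of them by little, and among the larger changes they became 9 and 2 for hypoxia response, 11 and 7 for lysosome, 4 and 1 for histone and 0 and 31 for ribosomal protein genes.

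The comparison of PKM2-knockdown with scramble ectosomes asks whether PKM2 in the donor cells matters for what their ectosomes do. With PKM2-knockdown ectosomes THP-1 cells had lower ER stress genes, and higher macrophage differentiation markers, MHC class II genes and glycolysis genes, than with scramble ectosomes. Each of these set calls was lost with an estimated correlation (adjusted p from 0.0828 to 0.849). That correlation was estimated from all libraries, the controls included, and its dependence on control replicate 3 was not tested. HSPA5 fell 7.98-fold, from 4552 to 570 CPM (adjusted p = 3.65e-08), AREG 68.9-fold, to 0.656 ± 0.160 CPM, and CXCL3 22.4-fold, to 10.7 CPM. The B-cell chemokine gene CXCL13 rose from 2.14 ± 0.277 to 468 ± 20.4 CPM, 219-fold (log2 fold change 7.77, SE 0.18, adjusted p = 4.15e-09). Of the 18437 genes 5782 were higher and 5583 lower, 11365 in all, of which 3319 and 1995 differed at least 2-fold.

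Among the 10 largest rises, RIPOR2 went from 0.502 to 59.4 CPM (117-fold), the chemokine gene CXCL14 from 2.003 to 58.4 CPM (29.1-fold), LUM, encoding the matrix proteoglycan lumican, from 0.459 to 19.1 CPM (41.6-fold), and the glucocorticoid-activating enzyme gene HSD11B1 from 0.240 to 11.4 CPM (46.1-fold). SLC44A2 rose 29.6-fold and FGL2 49.6-fold, or 82.7-fold without scramble replicate 2. HSPA7 and FCGR2C, which may share reads with near-identical genes, rose 157-fold and 70.3-fold and are uncertain. PNCK, which overlaps the more abundant SLC6A8 on the other strand, rose 35.6-fold and is uncertain too. Among the 10 largest falls, TNC, encoding the matrix protein tenascin C, went from 28.2 ± 0.155 to 0.145 ± 0.0910 CPM (183-fold), GDF15, a stress-induced cytokine gene, from 320 to 10.7 CPM (29.8-fold), and CST7 from 97.8 to 2.34 CPM (41.6-fold). OLAH fell 48.6-fold, the splicing regulator gene ESRP1 41.0-fold, the Notch ligand gene JAG1 28.5-fold, NRCAM 26.9-fold, the lipid synthesis gene GPAT3 24.4-fold and MDGA1 23.9-fold. Adjusted p of these 20 genes ran up to 1.06e-05.

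Of 21 amino acid and ER stress genes, 0 were higher and 20 lower with PKM2-knockdown than with scramble ectosomes (median log2 -1.83; adjusted p = 3.94e-12, and adjusted p = 0.617 with an estimated correlation). DNAJB9 fell 9.18-fold and SDF2L1 6.599-fold. Of 24 MAPK immediate-early and feedback genes, 3 rose and 16 fell (median log2 -0.95; adjusted p = 0.000449, and adjusted p = 0.849 with an estimated correlation), DUSP5 falling 10.2-fold and FOSB 7.04-fold. Of 33 ribosomal protein genes, 0 rose and 30 fell (median log2 -0.53; adjusted p = 0.000449, and adjusted p = 0.862 with an estimated correlation), RPS12 by 2.03-fold. Without control replicate 3, which is in neither group of this comparison, the counts were 0 and 21, 4 and 20, and 0 and 32. That library had median log2 differences from the other controls of -0.91, -0.81 and 0.23 for these lists.

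Of 19 macrophage differentiation markers, 14 were higher and 1 lower with PKM2-knockdown ectosomes (median log2 1.83; adjusted p = 8.63e-05, and adjusted p = 0.617 with an estimated correlation). CSF1R, the receptor of the growth factor M-CSF, rose from 84.96 to 351 CPM (4.13-fold) and TREM2 10.1-fold. All 11 MHC class II genes tested rose (median log2 1.89; adjusted p = 1.93e-06, and adjusted p = 0.0828 with an estimated correlation), with HLA-DRA 3.71-fold and HLA-DPA1 6.85-fold higher, although reads may be shared among HLA genes. Of 22 glycolysis genes, 16 rose and 2 fell (median log2 0.69; adjusted p = 0.00142, and adjusted p = 0.849 with an estimated correlation), with HK1 3.72-fold and PFKL 2.91-fold higher while PKM was lower. Of 23 cholesterol synthesis genes, 15 rose and 2 fell (median log2 0.45; adjusted p = 0.0279, and adjusted p = 0.862 with an estimated correlation), FDPS rising 4.06-fold. Of 16 progenitor and granule genes, 10 rose and 1 fell (median log2 0.68; adjusted p = 0.0271, and adjusted p = 0.849 with an estimated correlation), RNASE2 rising 12.2-fold. Control replicate 3 differed from the other controls by median log2 values of -0.37, 0.07, -0.38, -0.51 and 0.82 for these lists, and without it the counts were 14 and 3, 11 and 0, 17 and 3, 17 and 4, and 13 and 1.

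Of 32 cell cycle genes, 18 rose and 13 fell (median log2 0.73; adjusted p = 0.0406, and adjusted p = 0.849 with an estimated correlation). Its members MCM2 (4.41-fold) and CCNE2 (5.83-fold) rose, and CDC20 (4.96-fold) and PLK1 (3.28-fold) fell. The set call ended without scramble replicate 1, 2 or 3 (adjusted p = 0.0737, 0.0608 and 0.0612, in a range of 0.00583 to 0.849) and without control replicate 3 (adjusted p = 0.109).

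Other lists moved both ways or did not pass the set test between the 2 kinds of ectosomes. Of 29 cytokines and chemokines 12 rose and 11 fell (adjusted p = 0.152), CXCL2 falling 9.89-fold and LIF 4.73-fold. Of 20 NF-kB targets 4 rose and 6 fell (adjusted p = 0.586), of 20 STAT3 targets 5 rose and 8 fell (adjusted p = 0.174), and of 28 interferon genes 6 rose and 1 fell (adjusted p = 0.586), STAT2 rising 2.30-fold. Control replicate 3 had median log2 differences of -1.48, -0.41 and -2.07 from the other controls for these last 3 lists, and without it the counts were 4 and 12, 8 and 10, and 12 and 10. Of 13 classically activated markers 6 rose and 2 fell (adjusted p = 0.506), with GBP1 6.76-fold higher and IRF1 3.09-fold lower. Of 11 alternatively activated markers 8 rose and 2 fell (adjusted p = 0.129), with CD209 3.26-fold higher. Of 24 myeloid transcription factors 5 rose and 11 fell (adjusted p = 0.174, but 0.0294 without control replicate 3), with FOSL2 2.54-fold and KLF4 3.45-fold lower. Of 18 LXR target and lipid handling genes 10 rose and 1 fell (adjusted p = 0.0858, but 0.0316 without control replicate 3 and 0.0227 with no filter on low counts, up to 0.617 among its alternatives). Of 19 hypoxia response genes 9 rose and 2 fell (adjusted p = 0.549), NDRG1 rising 7.52-fold and VLDLR falling 2.51-fold. Of 24 lysosome genes 12 rose and 6 fell (adjusted p = 0.466), of 20 matrix genes 7 rose and 5 fell (adjusted p = 0.505), of 7 hepatocyte transcripts 3 rose and 0 fell (adjusted p = 0.549), of 13 mitochondrially encoded genes 3 rose and 6 fell (adjusted p = 0.903), and of 9 histone genes 2 rose and 2 fell (adjusted p = 0.778). The counts without control replicate 3 were 13 and 13 for cytokines, 8 and 3 for classically and 9 and 2 for alternatively activated markers, 8 and 15 for myeloid transcription factors, 13 and 2 for LXR target, 11 and 3 for hypoxia, 12 and 7 for lysosome, 12 and 5 for matrix, 4 and 0 for hepatocyte and 3 and 4 for histone genes, and the same for mitochondrially encoded genes. Median, mean and set test differed in sign for the cytokine and mitochondrially encoded lists.

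Adjusted over the list alone, the counts between the 2 kinds of ectosomes changed for macrophage markers (14 and 2), classically activated markers (6 and 3), interferon genes (5 and 1), LXR targets (10 and 2), MAPK genes (4 and 16) and ribosomal proteins (0 and 31) only. Every library of 1 group lay above every library of the other for 74.5% of the genes (chance 10%). Library totals alone moved the median log2 fold change of all genes by 0.17 and the share of calls that were rises from 50.9% to 61.9%. The median of the mitochondrially encoded genes then changed from -0.05 to 0.13, with 5 higher and 0 lower. Counts of most other lists changed as well. They became 0 and 22 for ribosomal protein, 0 and 17 for ER stress, 4 and 13 for MAPK and 12 and 2 for hypoxia genes. Myeloid transcription factors then had 9 and 11, progenitor and granule genes 12 and 0, and classically activated markers 6 and 1. NF-kB targets had 4 and 3, glycolysis genes 18 and 1 and histone genes 3 and 1.

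**Figure D3:**
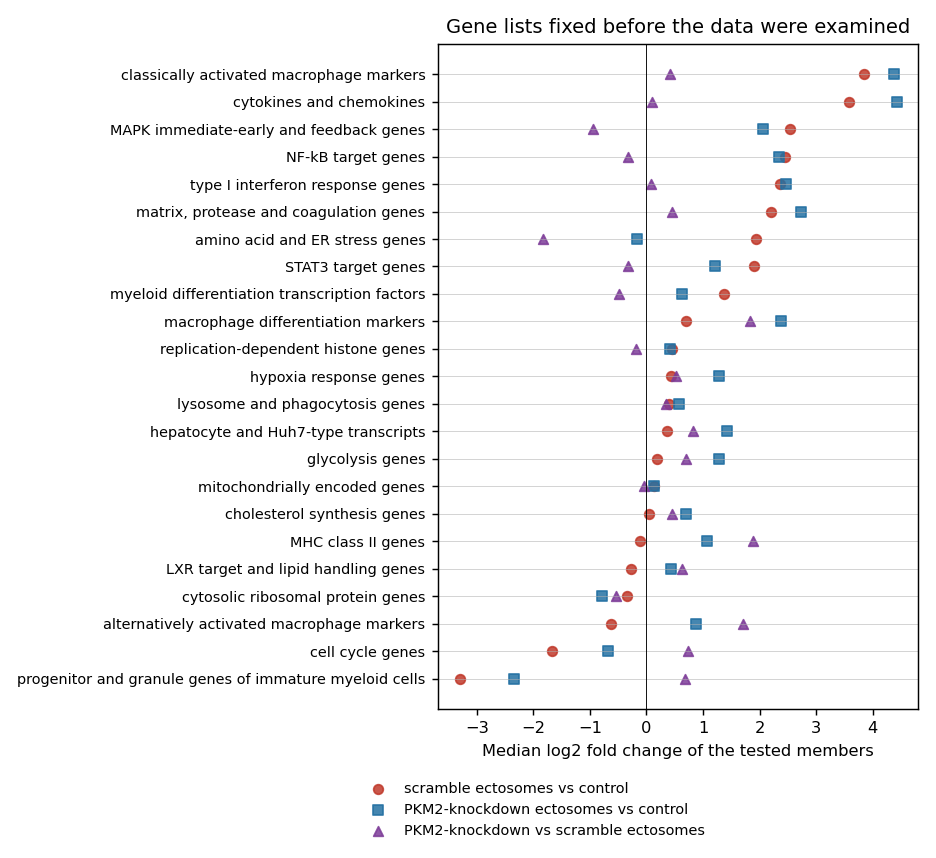
Median log2 fold change (x axis) of the 23 gene lists (y axis) in the 3 comparisons, 1 marker per comparison, defined in the legend. Cytokines and NF-kB targets lie far above 0 against control with both kinds of ectosomes (3.58 and 4.43, 2.45 and 2.34), and amino acid and ER stress genes lie at 1.94 with scramble ectosomes, -0.17 with PKM2-knockdown ectosomes and -1.83 between them.

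PKM2-knockdown ectosomes were compared with control to see what remains of the response with ectosomes labelled as PKM2 knockdown. Cytokines, NF-kB targets, interferon genes and macrophage markers were higher than in control cells, as were MHC class II and glycolysis genes, and progenitor, cell cycle and ribosomal protein genes were lower. With an estimated correlation the call of MHC class II genes held (adjusted p = 0.0479) and the others of these were lost (adjusted p from 0.0519 to 0.383). IL1B stood at 2024 ± 67.0 CPM against 4.99 ± 4.13 CPM in control cells, and CXCL13 rose 1834-fold (log2 fold change 10.84, SE 0.22, adjusted p = 6.76e-10). Of the 18437 genes 4978 were higher and 4926 lower, 9904 in all, of which 2682 and 1331 differed at least 2-fold. The 5 largest rises were IGFBP5, at 187 ± 12.3 CPM against 2 control reads (ratio 5626, 95% interval 1557 to 46464, with a fitted fold of 4749 or, without control replicate 2, 3098), CXCL13, MUC5AC (8.85 ± 0.709 CPM against 0 reads, at least 177-fold), RGS1, a regulator of G-protein signalling (0.608 to 512 CPM, 808-fold), and NRG1 (2.83 ± 0.502 CPM against 0 reads, at least 56.4-fold). The 5 largest falls were SERPINB2 (98.6-fold, or 27.4-fold without control replicate 3), F13A1 (72.4-fold), TERT (47.8-fold, or 26.4-fold without control replicate 3), the non-coding MIR9-3HG (29.1-fold) and SERPINB10 (24.4-fold, or 8.53-fold without control replicate 3).

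Of 29 cytokines and chemokines, 28 rose and 0 fell with PKM2-knockdown ectosomes (median log2 4.43, also with CCL1 at its bound; adjusted p = 1.53e-28, and adjusted p = 0.0519 with an estimated correlation). CCL20 rose 88.3-fold and IL12B 45.5-fold. All 20 NF-kB targets rose (median log2 2.34; adjusted p = 9.68e-17, and adjusted p = 0.150 with an estimated correlation), SOD2 by 8.11-fold. Of 13 classically activated markers, 11 rose and 0 fell (median log2 4.37; adjusted p = 1.24e-14, and adjusted p = 0.0242 with an estimated correlation), with CCR7 173-fold and GBP1 31.3-fold higher. Of 28 interferon genes, 27 rose and 0 fell (median log2 2.47; adjusted p = 8.05e-08, and adjusted p = 0.383 with an estimated correlation). Of 20 STAT3 targets, 14 rose and 3 fell (median log2 1.22; adjusted p = 9.15e-05, and adjusted p = 0.277 with an estimated correlation), SOCS3 rising 23.5-fold and IL6R falling 2.62-fold. Of 24 MAPK genes, 21 rose and 2 fell (median log2 2.06; adjusted p = 2.03e-07, and adjusted p = 0.269 with an estimated correlation), IER3 rising 79.8-fold. In control replicate 3 these lists had median log2 differences of -1.23, -1.48, -1.11, -2.07, -0.41 and -0.81 from the other controls. Without it 28 and 0, 20 and 0, 12 and 0, 27 and 0, 14 and 6, and 21 and 2 members rose and fell.

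Of 19 macrophage differentiation markers, 14 rose and 1 fell against control (median log2 2.38; adjusted p = 7.56e-08, and adjusted p = 0.141 with an estimated correlation), with CSF1R 9.89-fold and GPNMB 18.2-fold higher. Of 11 MHC class II genes, 10 rose and 0 fell (median log2 1.07; adjusted p = 1.66e-07, and adjusted p = 0.0479 with an estimated correlation), HLA-DRA by 9.17-fold. Of 20 matrix, protease and coagulation genes, 16 rose and 2 fell (median log2 2.74; adjusted p = 9.96e-12, and adjusted p = 0.0519 with an estimated correlation), with FN1, the fibronectin gene, 16.4-fold higher. Of 24 lysosome and phagocytosis genes, 20 rose and 1 fell (median log2 0.58; adjusted p = 0.000267, and adjusted p = 0.150 with an estimated correlation), the cathepsin gene CTSB rising from 148 to 955 CPM. Of 24 myeloid transcription factors, 13 rose and 4 fell (median log2 0.62; adjusted p = 0.00414, and adjusted p = 0.469 with an estimated correlation), RUNX3 rising 9.32-fold and IRF8 falling 4.998-fold. Control replicate 3 had median log2 differences of -0.37, 0.07, -0.82, -0.19 and -0.76 from the other controls for these lists, and the counts without it were 14 and 1, 10 and 0, 17 and 2, 20 and 1, and 13 and 6.

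Glycolysis, hypoxia response and cholesterol synthesis genes rose too. Of 22 glycolysis genes, 20 rose and 2 fell (median log2 1.29; adjusted p = 7.92e-09, and adjusted p = 0.220 with an estimated correlation), the lactate transporter gene SLC16A3 going from 250 to 1259 CPM. Of 19 hypoxia response genes, 16 rose and 2 fell (median log2 1.27; adjusted p = 0.000682, and adjusted p = 0.311 with an estimated correlation), ADM by 27.6-fold. Of 23 cholesterol synthesis genes, 18 rose and 1 fell (median log2 0.71; adjusted p = 0.00108, and adjusted p = 0.469 with an estimated correlation), INSIG1 by 2.67-fold. Progenitor and granule genes fell, 14 of 16, with 0 higher (median log2 -2.34; adjusted p = 1.76e-10, and adjusted p = 0.141 with an estimated correlation), as did 31 of 32 cell cycle genes, with 0 higher (median log2 -0.68; adjusted p = 2.37e-08, and adjusted p = 0.141 with an estimated correlation), and all 33 ribosomal protein genes (median log2 -0.78; adjusted p = 5.80e-12, and adjusted p = 0.275 with an estimated correlation). MYB fell 5.75-fold, MCM2 1.72-fold and RPS2 2.23-fold. The median log2 differences of control replicate 3 for these 6 lists were -0.38, -0.50, -0.51, 0.82, 0.16 and 0.23, and without it the counts were 20 and 2, 16 and 2, 18 and 1, 0 and 14, 0 and 32, and 0 and 33.

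The amino acid and ER stress genes, of which 4 were higher and 9 lower than in control cells, did not pass the set test (median log2 -0.17; adjusted p = 0.503), with HSPA5 1.67-fold higher and CEBPG 1.93-fold lower. Without control replicate 3, whose median for this list was -0.91 from the other controls, 5 were higher and 11 lower and the list was lower as a set (adjusted p = 0.00420, in a range of 0.00420 to 0.905). Of 18 LXR target and lipid handling genes 9 rose and 3 fell (adjusted p = 0.0769, but 0.0293 without PKM2-knockdown replicate 1 and 0.0149 with no filter, in a range of 0.0149 to 0.277), ABCA1 rising 5.76-fold. Of 11 alternatively activated markers 5 rose and 3 fell (adjusted p = 0.936), of 9 histone genes 4 rose and 0 fell (adjusted p = 0.265), and of 13 mitochondrially encoded genes 2 rose and 0 fell (adjusted p = 0.730). Of 7 hepatocyte transcripts 4 rose and 2 fell (adjusted p = 0.815). SERPINA1, which monocytes also express, rose 17.8-fold, or 32.7-fold without control replicate 2, and GPC3 fell 2.81-fold. With control replicate 3 left out the counts were 9 and 5 for LXR target genes, 5 and 4 for alternatively activated markers and 6 and 0 for mitochondrially encoded genes, and the same for histone and hepatocyte genes. Adjusted over the list alone, the counts changed for interferon genes (28 and 0), lysosome genes (22 and 1) and matrix genes (17 and 2) only. Every library of 1 group lay above every library of the other for 60.5% of the genes (chance 10%), and library totals alone moved the median log2 fold change of all genes by -0.03, with counts of 19 and 2 for glycolysis, 19 and 2 for lysosome and 2 and 1 for mitochondrially encoded genes. Over the 3 comparisons the set calls that held with an estimated correlation were those of classically activated markers and MHC class II genes with PKM2-knockdown ectosomes against control.

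**Figure D4:**
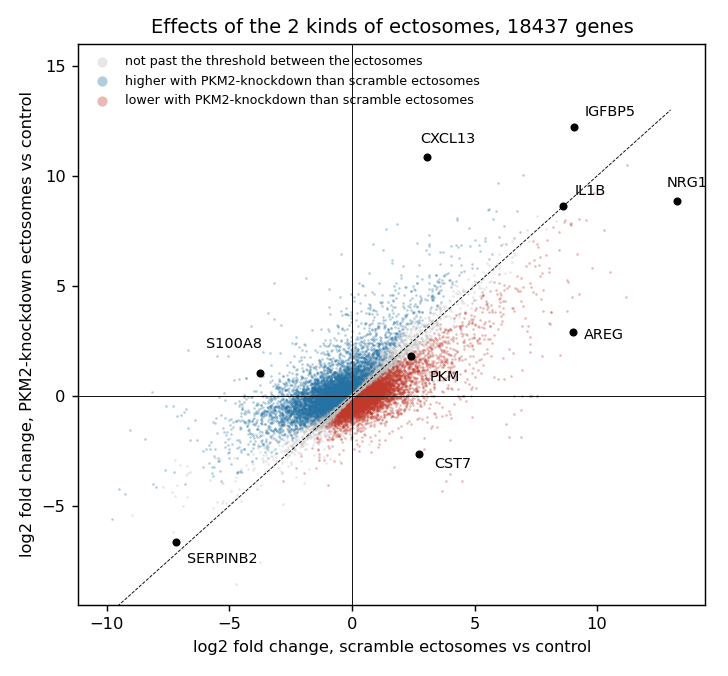
Log2 fold change against control of each gene with scramble ectosomes (x axis) and with PKM2-knockdown ectosomes (y axis), 1 point per gene (18437), coloured by whether it passed the threshold between the 2 kinds of ectosomes. IL1B lies near the diagonal, AREG, NRG1 and CST7 below it and CXCL13, IGFBP5 and S100A8 above it, and the position of NRG1, with 0 control reads, depends on the prior count of the fit.

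Many genes moved by scramble ectosomes differed the other way between PKM2-knockdown and scramble ectosomes. The amount and preparation of the 2 kinds were not tested, so their part in this cannot be told from that of PKM2. Of 12492 genes called with scramble ectosomes, 7851 (62.8%) differed in the opposite direction between PKM2-knockdown and scramble ectosomes, 4019 being higher with scramble ectosomes and lower again with the knockdown, as HSPA5, AREG and GDF15, and 3832 the reverse. A further 964 moved further the same way, as IGFBP5. These comparisons share the scramble-ectosome libraries, which by itself gives opposite signs. Independent lists of these sizes would overlap by 3849 genes in opposite directions. Simulations without any effect, 20 in all, gave at most 0, which follows from there being few or no calls without an effect and says nothing on the size of the overlap. The correlation of the log2 fold changes across genes was -0.65 (simulated -0.50) and their covariance -1.27 (simulated -0.04, difference -1.23). Part of the excess may come from the shared libraries, since 3 libraries cannot be split into parts of 2 or more.

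Genes moved the same way by both kinds of ectosomes numbered 6431, 51.5% of those called with scramble ectosomes, 3290 being higher with both, as IL1B and MUC5AC, and 3141 lower with both, as TERT and F13A1. Independent lists would share 3356 genes in the same direction (simulated without any effect at most 0, for the same reason). Across genes the correlation was 0.68 (simulated 0.51) and the covariance 1.37 (simulated 0.04, difference 1.33), and part of this excess may come from the shared controls. In 1050 genes the 2 kinds of ectosomes moved expression in opposite directions against control. A total of 2626 genes lay between the other groups with PKM2-knockdown ectosomes, past the threshold from both, and 3911 lay beyond both, 2082 above, as CXCL13 and CSF1R, and 1829 below. Of these, 894 lay at least 2-fold above and 184 at least 2-fold below both. The counts of 1050, 2626 and 3911 genes come from comparisons that share libraries. No overlap of independent lists was computed for them. Without control replicate 3, 13640, 13617 and 10997 genes were called in the 3 comparisons, including 96.9%, 99.9% and 95.6% of those called with all libraries, with 0 in the opposite direction.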

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

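Of the tests in this part, the one of a weaker form of the scramble-ectosome response and the leaving out of control replicate 3 for genes beyond both other groups were chosen only after the result was seen. The results here stand out by a difference between groups: the 2 kinds of ectosomes moved a gene in opposite directions against control, and the test of PKM2-knockdown against scramble ectosomes, which is the test of that difference, passed the threshold. This held for 1050 genes, 14.04% of those called against control with both kinds. Of them, 574 were higher with scramble and lower with PKM2-knockdown ectosomes and 476 the reverse. All genes called in opposite directions against control passed the test of the difference, so that test removed none. No overlap of independent lists was computed for this count.

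Among the genes named for the largest differences, 5 were lower with scramble and higher with PKM2-knockdown ectosomes than in control cells. The log2 difference between the 2 effects was 7.29 for HSPA7 (-4.11 and 3.18 against control), 6.14 for FCGR2C (-2.90 and 3.23), 5.63 for FGL2 (-3.64 and 1.99, the difference being 6.37 without scramble replicate 2), 5.53 for HSD11B1 (-4.80 and 0.73) and 4.89 for SLC44A2 (-2.92 and 1.97). HSPA7 and FCGR2C have near-identical copies, and reads exchanged with these were not tested for. In the other direction the difference was -5.38 for CST7 (2.75 and -2.63 against control), -5.36 for ESRP1 (2.93 and -2.43), -4.83 for JAG1 (2.93 and -1.90) and -4.58 for MDGA1 (3.68 and -0.90).

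The pattern weighed here is that PKM2-knockdown ectosomes moved 3911 genes beyond both other groups. The comparisons behind this count share the PKM2-knockdown libraries, which by itself gives calls of the same sign. No overlap of independent lists was computed for it, so an excess over chance was not tested. The 3911 genes are 21.2% of the genes tested. That share is the pattern itself, so it argues only against a response that was that of scramble ectosomes made weaker in every gene. Control replicate 3 does not account for the pattern, since 97.6% of these genes lay beyond both without it, and gene length and GC content explained a share of 0.0322 of the variance of their log2 fold change. The amount and preparation of the 2 kinds of ectosomes and a response of another kind to PKM2-knockdown ectosomes were not tested and stay open.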

How the results depend on the processing

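Of the alternatives in this part, scaling by library totals alone, and leaving out control replicate 3 for the comparison of the 2 kinds of ectosomes, were chosen only after the result was seen. The 3 counts (genes changed, scramble ectosomes vs control; genes changed, PKM2-knockdown ectosomes vs scramble ectosomes; genes changed, PKM2-knockdown ectosomes vs control) and the 2 overlaps (genes moved by scramble ectosomes and moved the other way by PKM2 knockdown, and genes moved the same way by both kinds of ectosomes) stayed within 1.5 times their value under DESeq2-type size factors, no filter on low counts, the DESeq2 Wald test, limma-voom, the replicate block and each left-out replicate, and so did the 3 counts in a fit of only the 2 groups compared. An absolute log2 fold change of at least 1 lowered them by its construction, to 6748, 5314 and 4013 genes and overlaps of 3445 and 2557. With 1 replicate of the groups compared left out at a time the counts ran from 11485 to 13640, from 10175 to 10549 and from 8399 to 10997, and, with 1 of the 9 libraries left out, the overlaps from 6965 to 9434 and from 5589 to 7074. Control replicate 3 is in neither group of the comparison of the 2 kinds of ectosomes, and without it that count was 13617. With the replicate number as a block they were 12179, 11035, 9401, 7597 and 6114. The residuals of libraries of the same number correlated from -0.160 to 0.118, and those of different numbers from -0.122 to 0.0946. Between the 2 kinds of ectosomes the same-number pairs gave 0.118, -0.0114 and 0.0955, and the highest other pair 0.0254. These values do not settle whether the numbers mark pairs.

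No result past the threshold changed direction. The direction of 3 set tests that passed neither way did: set test of cholesterol synthesis genes, scramble ectosomes vs control, without control replicate 3 (adjusted p = 0.614, from 0.610 to 0.890 with 1 replicate left out), set test of mitochondrially encoded genes, PKM2-knockdown vs scramble ectosomes, without scramble replicate 2 (0.965, from 0.792 to 0.965), and set test of alternatively activated macrophage markers, PKM2-knockdown ectosomes vs control, without control replicate 1 (0.840) or 3 (0.214, from 0.214 to 0.981) and with no filter (0.917). Of 59 results of named genes, all 59 kept their side of the threshold under DESeq2-type size factors, limma-voom, no filter and the replicate block, and 58 in a fit of only the 2 groups compared, where CCL1 was once removed by the filter. With the DESeq2 Wald test 56 did, CCL1 was called for scramble ectosomes against control, and SERPINB2 had no adjusted p in 2 comparisons. With 1 replicate of the groups compared left out, 352 were the same, 1 gained its call (CCL1) and 1 lost it (PKM between the 2 kinds of ectosomes). PKM lost that call with library totals alone as well (log2 fold change -0.42). Of 69 set tests, 35 lost their call with an estimated correlation and 34 were the same, while with no filter 5 gained a call. Of the set tests with 1 replicate of the groups compared left out, 400 were the same, 7 gained a call, 3 lost it and 4 are those that changed direction. Between the 2 kinds of ectosomes, leaving out control replicate 3 also gave calls to myeloid transcription factors (adjusted p = 0.0294) and LXR targets (0.0316) and ended that of cell cycle genes (0.109). As control replicate 3 is in neither group, it can act here only through the row filter, scaling and spread estimated from all libraries. A fit of only the 2 groups compared also called more genes, 13138 against 11365. Which of these moved the set calls was not tested. Genes of low count were recovered less well in simulation. Of genes changed 4-fold under 5 CPM, 13 of 27 (48.1%) were recovered for scramble ectosomes against control. The shares were 82.6% between the 2 kinds of ectosomes and 72.0% for PKM2-knockdown ectosomes against control. Depth was not varied, and the simulation changed far fewer genes than the data called.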

Other observations

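Of the tests in this part, both tests of mixed RNA and the test of Huh7 RNA carried over were chosen only after the result was seen, as were the gene groups of the next paragraph and scaling by library totals alone.

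Of 5 EGF-family ligand genes tested, 5 rose with scramble ectosomes, 5 were lower with PKM2-knockdown than with scramble ectosomes and 4 were above control with the knockdown. HBEGF stood at 8.85, 242 and 88.0 CPM in control cells, with scramble and with PKM2-knockdown ectosomes. The alarmin genes S100A8, S100A9 and S100A12 all fell with scramble ectosomes and all rose with PKM2-knockdown ectosomes, S100A8 standing at 84.98, 6.26 and 174 CPM and S100A9 at 132, 10.8 and 245 CPM. Of 22 ER translocon, chaperone and signal peptidase genes, 20 rose and 1 fell with scramble ectosomes, 0 rose and 21 fell between the 2 kinds, and 7 rose and 5 fell (6 with library totals alone) with PKM2-knockdown ectosomes against control. HYOU1 stood at 214, 2835 and 244 CPM and HSP90B1 at 391.7, 2960 and 376 CPM. Of 6 NADPH oxidase subunit genes, 4 rose with scramble ectosomes, 5 rose with PKM2-knockdown ectosomes, and between the 2 kinds 3 rose and 2 fell (1 with library totals alone). CYBB stood at 50.2, 137 and 378 CPM. Of 8 complement genes, 5 rose and 2 fell with scramble ectosomes, 7 rose (6 with library totals alone) and 1 fell with PKM2-knockdown ectosomes, and 6 rose and 2 fell between the 2 kinds, C3 standing at 17.8, 76.3 and 1089 CPM. Of 8 immune checkpoint and TNF-receptor genes, 7 rose with scramble and 8 with PKM2-knockdown ectosomes, and between the 2 kinds 1 rose (2 with library totals alone) and 2 fell, CD274 standing at 0.531, 22.2 and 13.3 CPM.

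For each comparison the 6 libraries make 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, called as many genes as it did: 12492, 11365 and 9904, the highest other split calling 0 each time. For genes moved the other way by the knockdown, 1 of 100 assignments of the 9 libraries to 3 groups gave as many as the real 7851, the highest other being 5717, in which control replicate 3 and PKM2-knockdown replicate 1 changed places. For genes moved the same way by both kinds of ectosomes it was 1 of 100, with 6431 in the real groups and 5646 in the highest other. A grouping that calls few genes has a small overlap whatever the real one, so this says nothing on the size of the overlaps among the genes called.

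Control replicate 3 stood apart from control replicates 1 and 2. Sequencing depth does not account for it, since with all thinned to 1 depth its median distance from control replicate 1 was 2.48 times that of control replicate 2, and length and GC content explained a share of 0.0503 of the variance. RNA of ectosome-treated cells in it would raise genes near 0 in the other controls, yet over 11 such genes the median log2 ratio was -1.18. These genes had means under 1 CPM in control replicates 1 and 2 (pseudocount 0.05 CPM), so the ratio rests on low counts. Lists raised by ectosomes also lay lower in control replicate 3, so this adds little to them. RNA of ectosome-treated cells in control replicates 1 and 2 would need 16.1% of the ectosome level, while the genes named for the largest rises stood at 0.263%. Culture or handling of these cells may differ but was not tested, and no biological explanation was tested.

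PKM transcript was higher with both kinds of ectosomes. RNA carried over in the proportions of Huh7 cells would bring their abundant transcripts, yet albumin reached at most 0.524 CPM in an ectosome library. Albumin ran from 0.0552 to 0.172 CPM in control cells and from 0.0903 to 0.144 with scramble ectosomes. With PKM2-knockdown ectosomes it was higher, from 0.328 to 0.524 CPM, at no more than 10 reads per library. Other hepatocyte transcripts did rise with PKM2-knockdown ectosomes, SERPINA1, which monocytes also express, to between 34.6 and 41.5 CPM (0.552 to 3.79 in control cells) and APOA2 to between 4.13 and 5.30 CPM (0.938 to 2.41), so selected RNA carried over was not excluded. Scaling does not account for the rise, as the lowest log2 fold change of PKM against control was 1.79 under the other 2 scalings. A response of the THP-1 cells may be put forward only as a hypothesis, found and tested on the same data.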
